A study of Caenorhabditis elegans with 4 samples.

How the data were processed

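Caenorhabditis elegans N2 young adults grown on Bacillus subtilis strain 67 or on Escherichia coli OP50 were compared on 4 two-colour Agilent arrays. Per the labels' protocols, about 200 hermaphrodites per biological replicate were collected into TRIzol, and 500 to 1000 ng of total RNA was labelled with Cy3 or Cy5 with the Quick Amp kit after addition of Agilent's spike-in controls. Each array is 1 biological replicate, per the labels; replicates 1 and 2 are forward arrays (Bacillus in Cy5) and replicates 3 and 4 are dye-swapped. Each array carries its own pair of RNAs, so the test is of its ratio against 0.

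The values are log2 ratios of the channels of each array as deposited by the authors. The submitters' processing notes name limma, with no version or steps; the base of the logarithm is taken as 2 because limma's ratios are on that scale. Background correction, centring, scaling between arrays and direction are not given in the sources used here, nor is a genome build. The medians over spots were -0.05, -0.06, -0.03 and -0.03 in replicates 1 to 4. Scanner files, channel intensities and backgrounds were not used here, so dim or saturated spots could not be set apart. A bias that depends on brightness, or ratios compressed in dim spots, would therefore pass into the values.

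Direction followed a rule fixed before the data were examined: swapped arrays were to be turned if they correlated negatively with forward arrays, and left if positively. All 6 array pairs correlated positively, between 0.624 and 0.843 over spots, so no sign was changed, and Bacillus over OP50 is the likely direction from the order in the titles. If the true direction is the opposite, every sign turns and higher and lower exchange in every count, while the totals of calls stay. No array pair was identical.

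Of 45220 spots, 1097 had no value on any array, 0 had values on some arrays only and 44123 had values on all 4. The platform annotation listed 27263 spots with 1 gene symbol and 0 with several, and all 27263 symbols were current in a RefSeq gene table of assembly WBcel235, used for names alone. The accessions of 19293 spots matched that table, and 98 spots whose symbol and accession named different genes were left unnamed. No gene was listed for 16860 measured spots (38.2%), which are unnamed here and not without a gene. Gene values are means over a gene's spots: 10509 of 15042 genes had 1 spot and 4533 had at least 2, and for 3200 of those 4533 the spots shared a sign. Naming was checked by setting the first 2 spots of each of the 4533 genes against each other (Pearson's r 0.858 across genes, and 0.000783 after shuffling). Paralogs with similar sequence may share signal on a spot.

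Genes and spots were tested with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, with no covariate. Gene lists, 43 in all and fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 4 members were measured, which held for 40; the lists of infection response genes and lysosomal lipases had 0 measured members and the propionate shunt 3. The dye effect was tested as a separate term. Errors are SDs over 4 arrays, SEs are limma's moderated values, and files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3; figures used matplotlib 3.10.9.

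Named genes followed a rule fixed before the data were examined: the 10 highest and 10 lowest ratios among genes past the threshold with the same sign on all 4 arrays; up to 2 highest and 2 lowest passing members of each list; and 16 genes named in advance whatever their value, of which 10 were measured. The others (gst-4, irg-1, rpl-2, sysm-1, hach-1 and hphd-1) are not analysed here.

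The scripts were tested on simulated data with the real spread of 15042 genes. In the gene comparison, of 50 genes each, log2 changes of -2, -1, 1 and 2 were recovered in 72%, 58%, 58% and 78%, and 9 of 14842 unchanged genes were called. A pure dye effect of 1.5 in 200 genes was called as a change in 0 and by its own term in 106. That effect had the same size on each array and cancels between forward and dye-swapped arrays, so few calls were bound to result. Dye effects of unequal size were not simulated. Of 20 shifted lists 20 were called, and of 20 unshifted lists 0. The simulated genes were drawn independently of each other. False calls in lists whose members move together were therefore not tested, and the estimated correlation of the real proteasome list was 0.96.

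Alternatives were a dye term, centring on each array's median, equal scale between arrays, array weights, leaving out each replicate, each dye orientation alone, a robust variance prior, the median over spots, genes with at least 2 spots of one sign, stricter thresholds, camera with an estimated correlation and fry. Centring on housekeeping lists (ribosomal, respiratory chain, proteasome and vacuolar ATPase) and on muscle markers was added after seeing the data.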

Results

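Gene expression was compared between Caenorhabditis elegans grown on lawns of Bacillus subtilis strain 67 and animals grown on Escherichia coli OP50, the usual laboratory food of this nematode. The animals were young adult hermaphrodites of the wild-type strain N2, grown from synchronised embryos at 20 °C, with about 200 animals per biological replicate. RNA of both foods was hybridised together on each of 4 two-colour Agilent arrays, 1 array per biological replicate. The Bacillus-fed RNA carried Cy5 in replicates 1 and 2 (forward arrays) and Cy3 in replicates 3 and 4 (dye-swapped arrays). The question was which transcripts differ between animals raised on the 2 bacteria. The value table held 45220 spots, of which 44123 had a log2 ratio on all 4 arrays, and the named spots covered 15042 genes. No channel intensities were used. The spread of the ratios differed between arrays, with an SD over spots of 0.78, 1.23, 0.57 and 0.61 in replicates 1 to 4. The arrays correlated across spots with Pearson's r between 0.624 and 0.843, spots not being independent replicates. All ratios are given as Bacillus over OP50, which is the likely direction and is not stated in the sources used here. Its basis is that the titles and the design name Bacillus before OP50. The positive correlation of forward and dye-swapped arrays shows that the 4 arrays share a direction and not which one. If the direction is the opposite, higher and lower exchange in every value, count, share and ranking below.

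The largest ratios included lysozyme genes on the higher side, where 4 of 15 rose and 1 fell, and yolk protein genes on the lower side, where 2 of 6 fell. The lysozyme gene lys-10 had the highest ratio of all called genes (the lowest, if the direction is the opposite), with a log2 ratio of 6.65 ± 0.40 (SD, n = 4), or 101-fold (SE 0.17, adjusted p = 0.00696). The invertebrate-type lysozyme ilys-3 followed at 5.34 ± 0.51, or 40.6-fold (adjusted p = 0.0119). The yolk protein genes vit-3 and vit-1 lay at the other end, at -4.37 ± 1.52 and -3.87 ± 1.04 (adjusted p = 0.0356 and 0.0240). Over all 15042 genes, limma called 1306 at an adjusted p under 0.05, of which 967 were higher and 339 lower on Bacillus. These are 6.43% and 2.25% of all genes, the shares against which the counts in each list are to be read. All 1306 had the same sign on all 4 arrays, which passing a test of 4 ratios against 0 all but requires. Of all genes, called or not, 49.5% did. A change of at least 2-fold was reached by 465 of the higher and 142 of the lower genes.

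The remaining 8 of the 10 highest genes were F53A9.8 (4.97 ± 1.29), F46C5.1 (4.65 ± 0.94), the cytochrome P450 gene cyp-37B1 (4.54 ± 1.02), F01D5.3 (4.53 ± 0.57), the UDP-glucuronosyltransferase gene ugt-18 (4.46 ± 0.51), F21C10.11 (4.34 ± 0.53), the C-type lectin gene clec-52 (4.33 ± 1.42) and ech-9 (4.02 ± 1.61), of the enoyl-CoA hydratase family. After the yolk genes, the lowest ratios were those of cyp-35A3 (-3.74 ± 0.97), clec-210 (-3.43 ± 0.42), ugt-63 (-2.73 ± 0.49), clec-97 (-2.69 ± 0.80), cyp-35C1 (-2.69 ± 1.05), F23A7.8 (-2.46 ± 0.75), W04C9.4 (-2.45 ± 0.74) and pgp-1 (-2.39 ± 0.63), a P-glycoprotein transporter. Families with members at both ends thus included the C-type lectins, the cytochrome P450s and the UDP-glucuronosyltransferases. Without replicate 1, without replicate 3 or without replicate 4, limma called 0 genes (2695, 4269 and 4090 at an unadjusted p under 0.05). Without replicate 2 it called 1733, of which 1002 were among the 1306. The 3 models that follow called more genes in both directions. A dye term gave 1415 higher and 2523 lower (35.9% higher, against 74.0%), scaling the arrays alike 1518 and 2907 (34.3%), and array weights 1583 and 935 (62.9%).

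**Figure D1:**
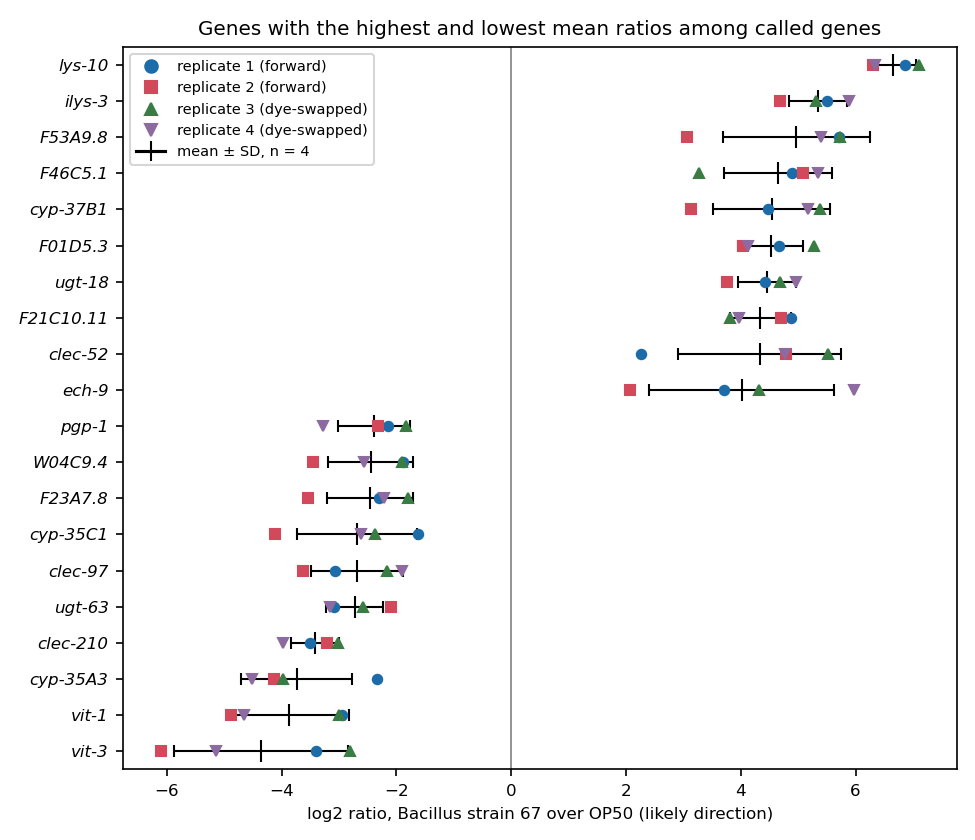
Log2 ratios (Bacillus over OP50, x axis) of the 10 highest and 10 lowest called genes; each symbol is 1 array, the bar is the mean and the whiskers are the SD over 4 arrays. By the rule that chose these genes, all 4 arrays lie on the same side of 0 for each. Means run from 6.65 for lys-10 to -4.37 for vit-3.

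Of the genes linked to defence against bacteria, the lysozyme, saposin-like and C-type lectin lists had higher means (adjusted p = 0.657 for each with an estimated correlation), and the lysozymes and lectins held calls in both directions. Among 15 lysozyme genes, 4 rose and 1 fell over all genes tested, and 7 rose and 2 fell when adjusted over the list alone. The lysozyme list mean was 1.26 ± 0.51 (SD of 4 array means, camera adjusted p = 0.0129, and adjusted p = 0.657 with an estimated correlation). The gene that fell was lys-1 (-1.43 ± 0.44, adjusted p = 0.0304), and lys-7, a lysozyme gene of pathogen responses, measured 2.95 (SE 0.68, n = 4) without passing the test (adjusted p = 0.0749). The lowest mean in the list was that of lys-2, picked after its value was seen, at -2.72 ± 1.34, which did not pass over all genes (adjusted p = 0.0643) and passed over the list alone (adjusted p = 0.0165). Of 22 saposin-like genes, whose products resemble pore-forming antimicrobial peptides, 5 rose and 0 fell (9 and 0 adjusted over the list alone), led by spp-8 (2.78 ± 1.18) and spp-23 (2.21 ± 0.90). The saposin-like list mean was 0.63 ± 0.60 (camera adjusted p = 0.00167, and adjusted p = 0.657 with an estimated correlation), with -0.24 in replicate 2 and 0.78 to 1.12 on the other arrays. Replicate 2 was also the lowest for the lysozymes (0.54 against 1.37 to 1.72) and for the intestine markers (-0.42 against 0.62 to 0.85). Of 243 C-type lectin genes, 21 rose and 4 fell (25 and 4 adjusted over the list alone). Among them were clec-172 (3.89 ± 0.39) with clec-52 upward and clec-210 and clec-97 downward. The shares of higher and lower lectin genes are near the 6.43% and 2.25% of all genes. The lectin list mean was 0.27 ± 0.05 (camera adjusted p = 0.0115, and adjusted p = 0.657 with an estimated correlation), while its median was 0.02.

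Of 61 antimicrobial peptide genes, cnc-10 rose (1.56 ± 0.36; 1 and 0 adjusted over the list alone). Of 6 thaumatin genes, thn-1 rose (1.66 ± 0.50; 3 and 0 adjusted over the list alone). Neither list passed the test (camera adjusted p = 0.101 and 0.0564). Of 9 effector genes that depend on the kinase PMK-1, dod-24 rose (2.27 ± 0.90) and K08D8.5 fell (-0.93 ± 0.34, but 0.21 when each array was centred on housekeeping lists). That centring raised the median of all genes by 1.15, so a sign that turns under it, here or below, follows from a shift common to all genes. When adjusted over the list alone 2 rose and 2 fell, and the list did not pass (camera adjusted p = 0.673). The lysozyme list also missed the threshold after scaling the arrays alike (adjusted p = 0.0549, against 0.0129 in the main setting and 0.657 at most over its alternatives).

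Genes of detoxification split in direction. Of 75 cytochrome P450 genes, 12 rose and 6 fell (18 and 7 adjusted over the list alone), with cyp-37B1 and cyp-32B1 (3.44 ± 0.61) upward and cyp-35A3 and cyp-35C1 downward. Of 64 UDP-glucuronosyltransferase genes, 11 rose and 7 fell (17 and 10 adjusted over the list alone), with ugt-18 and ugt-2 (2.32 ± 0.69) upward and ugt-63 and ugt-22 (-2.28 ± 0.67) downward. Of 46 glutathione S-transferase genes, 3 rose and 0 fell (0 and 0 adjusted over the list alone), including gst-42 (1.34 ± 0.50) and gst-33 (0.65 ± 0.24). That share of higher genes is near the 6.43% of all genes. The glutathione S-transferase list was shifted higher (mean 0.23 ± 0.15, camera adjusted p = 0.00545), and so, narrowly, was the P450 list (mean 0.04 ± 0.17, adjusted p = 0.0457). The glucuronosyltransferase list was not (adjusted p = 0.377). For both shifted lists adjusted p = 0.657 with an estimated correlation. The P450 call was lost without replicate 1 (mean 0.0016, adjusted p = 0.0649), without replicate 3 (mean -0.011, adjusted p = 0.109) and without replicate 4 (adjusted p = 0.0730). It was also lost after centring each array on its median (adjusted p = 0.0574), and without replicate 2 the mean was 0.11. None of 11 targets of the oxidative stress regulator SKN-1 passed limma's test, over all genes or adjusted over the list alone (list mean -0.28 ± 0.18, camera adjusted p = 0.341).

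In lipid and propionate metabolism, individual enzymes moved in both directions. Of 15 acyl-CoA synthetase and peroxisome genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone). The highest of the called genes were prx-12 (1.54 ± 0.36) and acs-17 (1.09 ± 0.37), and acs-1, an acyl-CoA synthetase of branched-chain fatty acid metabolism, fell by 2.32 ± 0.30 on the log2 scale (adjusted p = 0.0124). Of 31 genes of fatty acid beta-oxidation, 3 rose and 2 fell (4 and 2 adjusted over the list alone), with ech-9 and ech-8 (1.38 ± 0.27) upward and ech-6 (-1.17 ± 0.28) and kat-1 (-1.01 ± 0.37, but 0.14 when centred on housekeeping lists) downward. Of 19 genes of fatty acid desaturation and elongation, the delta-6 desaturase gene fat-3 rose (1.83 ± 0.77, adjusted p = 0.0499), with 0 and 0 adjusted over the list alone. The propionate shunt is an alternative route of propionate breakdown that is used when vitamin B12 is scarce. Of its 3 measured members, ech-6 fell, and acdh-1 (-1.19 ± 0.73, adjusted p = 0.0918) and alh-8 (0.12 ± 0.71, adjusted p = 0.818) did not pass. Adjusted over the list alone, 0 were higher and 2 lower. Of 6 genes of the B12-dependent route, mce-1 fell (-0.45 ± 0.08, but 0.70 when centred on housekeeping lists; 0 and 2 adjusted over the list alone; camera adjusted p = 0.0564). Of 4 genes of the methionine cycle, pmt-1, a methyltransferase of phosphatidylcholine synthesis, rose (1.94 ± 0.73; 1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.609).

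As a list, the acyl-CoA synthetase and peroxisome genes were shifted higher (mean 0.24 ± 0.46, camera adjusted p = 0.0334; adjusted p = 0.657 with an estimated correlation). They did not pass without replicate 1 (adjusted p = 0.0578), without replicate 4 (mean 0.070, adjusted p = 0.0730), after median centring (adjusted p = 0.0570) or after scaling the arrays alike (adjusted p = 0.0668). Their mean was 0.44 without replicate 2 and -0.054 on the forward arrays alone. The beta-oxidation and the desaturation and elongation lists did not pass (camera adjusted p = 0.528 and 0.294).

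Lists of the female germline and yolk had lower means on Bacillus, while few of their genes passed the test. The 27 oocyte and eggshell genes averaged -1.41 ± 1.01 (SD of 4 array means, camera adjusted p = 6.79e-06, and adjusted p = 0.657 with an estimated correlation). Of these, rme-2, the yolk receptor of oocytes, fell (-1.78 ± 0.63) while 26 did not pass (0 and 0 adjusted over the list alone). The 19 genes of germline meiosis and replication averaged -1.52 ± 1.11 (camera adjusted p = 3.28e-05, and adjusted p = 0.657 with an estimated correlation), with glh-1, a germ granule helicase, lower (-2.25 ± 0.74; 0 and 1 adjusted over the list alone). Of 6 vitellogenin genes, vit-1 and vit-3 fell (0 and 4 adjusted over the list alone), and vit-2 measured -0.71 ± 0.98 (adjusted p = 0.311). The vitellogenin list mean was -2.44 ± 1.13 (camera adjusted p = 0.0115, and adjusted p = 0.657 with an estimated correlation). The 41 sperm genes had 0 calls in limma, over all genes or over the list alone, with a list mean of 0.49 ± 0.75 (camera adjusted p = 0.0131, and adjusted p = 0.688 with an estimated correlation). The gene msp-3, a major sperm protein gene, measured 0.73 ± 1.63 (adjusted p = 0.515).

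Replicate 2 stood apart in these lists. Its mean was -2.86 for the oocyte and eggshell genes against -1.28, -0.84 and -0.64 in replicates 1, 3 and 4. It was -3.08 for the meiosis and replication genes against -1.56, -0.77 and -0.68, and 1.44 for the sperm genes against -0.34, 0.65 and 0.22. Without replicate 2 the sperm list no longer passed (mean 0.18, adjusted p = 0.170), whereas the oocyte, meiosis and vitellogenin lists passed without each replicate in turn at the preset correlation (an estimated one was not run there). Without replicate 2 the oocyte mean was -0.92, the meiosis mean was smaller by 1.52 times, and without replicate 1 the sperm mean was 0.77. On the forward arrays alone the vitellogenin list did not pass (adjusted p = 0.0611).

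The ribosomal, proteasome, respiratory chain and reticulum chaperone lists had lower means on Bacillus, and of these the ribosomal list alone held calls over all genes. Of 59 ribosomal protein genes, 25 fell and 0 rose over all genes tested (54 and 0 adjusted over the list alone). The lowest of the called genes were rpl-11.1 at -1.75 ± 0.53 and rpl-30 at -1.64 ± 0.48, and the list mean was -1.20 ± 0.48 (camera adjusted p = 2.88e-17, and adjusted p = 0.657 with an estimated correlation). The 29 proteasome genes had 0 calls in limma over all genes and 22 lower adjusted over the list alone, with a mean of -1.47 ± 0.99 (camera adjusted p = 1.36e-07, and adjusted p = 0.657 with an estimated correlation). The 27 respiratory chain genes (mean -0.74 ± 0.68, adjusted p = 0.000532, and adjusted p = 0.664 with an estimated correlation) and the 16 endoplasmic reticulum chaperone genes (mean -0.93 ± 0.74, adjusted p = 0.00490, and adjusted p = 0.657 with an estimated correlation) were shifted lower with 0 calls over all genes or over the list alone. The proteasome means were -1.39, -2.89, -0.90 and -0.70 in replicates 1 to 4, beside oocyte and eggshell means of -1.28, -2.86, -0.84 and -0.64. In these lists too replicate 2 lay lowest, at -1.86, -2.89, -1.75 and -1.96. Without it the respiratory chain mean was -0.41 and the chaperone mean -0.58, with adjusted p = 0.00217 and 0.000980 at the preset correlation. An estimated correlation was not run without replicate 2, and on all 4 arrays neither list passed camera with one (adjusted p = 0.664 and 0.657).

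Among single chaperones, hsp-4, the reticulum chaperone raised by unfolded proteins, measured -1.82 ± 1.36 (adjusted p = 0.116). Of 5 mitochondrial chaperone and unfolded protein response genes, hsp-60 (-1.12 ± 0.44) and hsp-6 (-1.34 to -0.41 over the 4 arrays, adjusted p = 0.0490) fell, though both lay above 0 when centred on housekeeping lists (0.021 and 0.15). The gene dve-1, a transcription factor of that response, rose (0.41 ± 0.08), though its 4 spots did not all share a sign. In all, 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.101). Of 17 vacuolar ATPase genes, vha-5 rose (1.11 ± 0.21; 1 and 0 adjusted over the list alone) and the list was not shifted (mean -0.14 ± 0.90, camera adjusted p = 0.921), with array means of 0.02, -1.45, 0.35 and 0.53. Without replicate 2 the mean of that list was 0.30 (adjusted p = 0.00624 with the preset correlation). On all 4 arrays adjusted p = 0.981 with an estimated correlation, which was not run without replicate 2. Of 14 histone genes, his-69 fell (-0.43 ± 0.13, but 0.71 when centred on housekeeping lists; 0 and 1 adjusted over the list alone; camera adjusted p = 0.132).

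**Figure D2:**
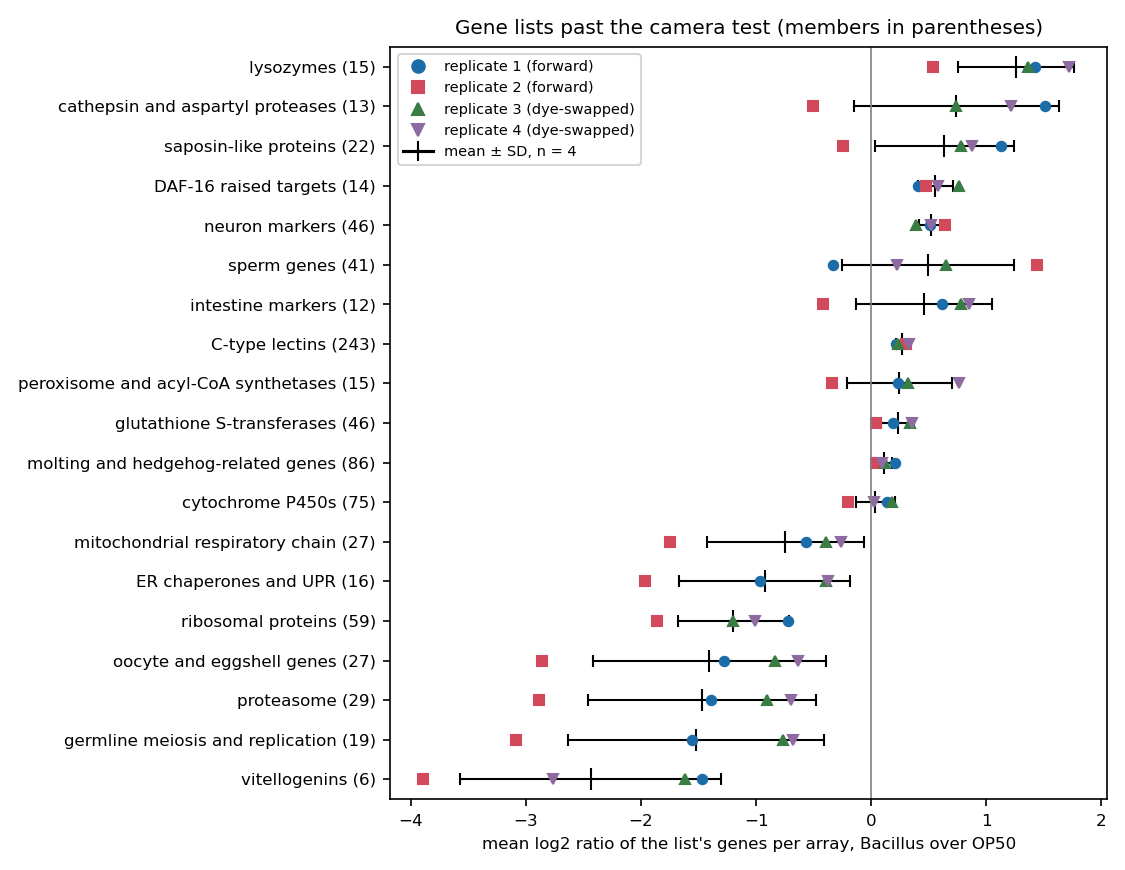
Mean log2 ratio (Bacillus over OP50, x axis) of the genes of each of the 19 lists that passed camera, 1 symbol per array, with the mean and the SD over 4 arrays; numbers of genes stand in parentheses. With an estimated correlation 0 of the 40 tested lists passed (lowest adjusted p = 0.657). Replicate 2 lies at -2.86 in the oocyte and eggshell list and -1.86 in the ribosomal list, below the other arrays.

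Of 46 neuron markers, 16 rose and 0 fell over all genes (31 and 1 adjusted over the list alone), led by the neuropeptide genes flp-4 (1.61 ± 0.51) and flp-20 (1.59 ± 0.44). The neuron list mean was 0.52 ± 0.10 (camera adjusted p = 6.11e-10, and adjusted p = 0.657 with an estimated correlation). Of 12 intestine markers, the transcription factor genes elt-2 (1.35 ± 0.05) and elt-7 (1.00 ± 0.17), regulators of intestinal identity, rose and pgp-1 fell (3 and 1 adjusted over the list alone). The intestine list mean was 0.46 ± 0.59 (camera adjusted p = 0.0223, and adjusted p = 0.657 with an estimated correlation), with -0.42 in replicate 2 and 0.62 to 0.85 on the other arrays (mean 0.75 without replicate 2). The 21 muscle markers had 0 calls in limma over all genes or over the list alone (mean -0.30 ± 0.33, camera adjusted p = 0.101). The intestine list did not pass without replicate 3 (adjusted p = 0.0662) or without replicate 4 (adjusted p = 0.0759). Of 19 regulators of stress and immunity, elt-2, also an intestine marker, was the single call (1 and 0 adjusted over the list alone; camera adjusted p = 0.207).

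**Figure D3:**
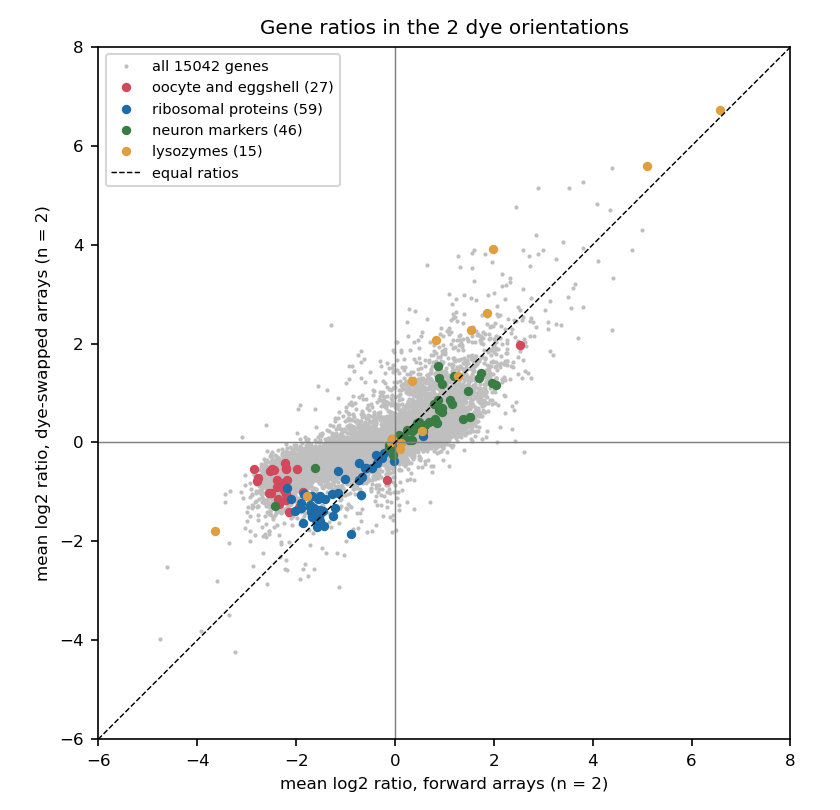
Mean log2 ratio (Bacillus over OP50) of each of 15042 genes on the 2 forward arrays (x axis) and the 2 dye-swapped arrays (y axis); coloured points are members of 4 lists and the dashed line marks equal ratios. Oocyte and eggshell genes lie further below 0 on the forward arrays (array means of -1.28 and -2.86) than on the dye-swapped arrays (-0.84 and -0.64), while lys-10 and ilys-3 lie near the dashed line.

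Of 13 cathepsin and aspartyl protease genes, cpr-3 rose (1.28 ± 0.18, with 3 and 0 adjusted over the list alone). The protease list mean was 0.74 ± 0.89 (camera adjusted p = 0.0131, and adjusted p = 0.657 with an estimated correlation). It was -0.51 in replicate 2 and 0.74 to 1.51 on the other arrays (mean 1.15 without replicate 2 and 0.48 without replicate 1). The intestine markers, which share asp-1 with this list, likewise lay at -0.42 in replicate 2 and 0.62 to 0.85 on the other arrays. Of 14 genes raised by the transcription factor DAF-16, nnt-1 (1.44 ± 0.36) and dod-3 (0.37 ± 0.10, but 0.01 as the median over its 5 spots) rose (3 and 0 adjusted over the list alone). The gene sod-3, its superoxide dismutase target, measured 0.61 ± 0.55 (adjusted p = 0.159) and the small heat shock gene hsp-16.2 -0.73 ± 0.93 (adjusted p = 0.275). The DAF-16 raised list was shifted higher (mean 0.56 ± 0.15, camera adjusted p = 0.0457, and adjusted p = 0.657 with an estimated correlation). It did not pass without replicate 2 (adjusted p = 0.0760) or without replicate 3 (adjusted p = 0.0662), after median centring (adjusted p = 0.0636), after scaling the arrays alike (adjusted p = 0.0543) or with array weights (adjusted p = 0.0629). Of 9 genes lowered by DAF-16, dod-24 rose (1 and 3 adjusted over the list alone; camera adjusted p = 0.371). Of 11 heat shock genes 0 passed limma's test (0 and 2 adjusted over the list alone; camera adjusted p = 0.673). Of 8 superoxide dismutases and catalases sod-4 rose (1.32 ± 0.25; 1 and 0 adjusted over the list alone; camera adjusted p = 0.610). Of 11 metal response genes smf-1, a metal transporter gene, rose (0.68 ± 0.12; 2 and 0 adjusted over the list alone; camera adjusted p = 0.175).

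Of 171 genes on the cuticle collagen list, 4 rose and 9 fell (4 and 9 adjusted over the list alone). They included col-153 (2.35 ± 0.55) and col-118 (1.31 ± 0.19) upward and col-93 (-1.92 ± 0.60) and col-43 (-1.76 ± 0.37) downward. The collagen list was not shifted (camera adjusted p = 0.688). Of 86 molting and hedgehog-related genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), including ptr-23 (1.49 ± 0.27) and ptr-3 (1.17 ± 0.34) upward and grd-4 (-0.40 ± 0.05, but 0.75 when centred on housekeeping lists) downward. The share of higher genes in the molting list is below the 6.43% of all genes. That list was shifted higher (mean 0.11 ± 0.07, camera adjusted p = 0.0165, and adjusted p = 0.657 with an estimated correlation). Of 41 zygotic embryo genes, sdz-24 rose (3.48 ± 0.41), and end-3 (-0.63 ± 0.19) and sdz-37 (-0.36 ± 0.10) fell, both lying above 0 when centred on housekeeping lists (0.51 and 0.79), with 1 and 1 adjusted over the list alone (camera adjusted p = 0.0863). Of 10 pharyngeal cuticle genes, 0 passed limma's test over all genes or over the list alone (camera adjusted p = 0.851).

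The protease and molting lists did not pass without replicate 1 (adjusted p = 0.0736 for both). Over all 40 tested lists, camera with its preset correlation placed 12 higher and 7 lower. With an estimated correlation it placed 0 (1 at an unadjusted p under 0.05). That setting raised p even where the estimate lay below the preset 0.01. The unadjusted camera p went from 0.0217 to 0.0925 for the DAF-16 raised targets (estimate -0.065). It went from 0.0283 to 0.110 for the thaumatins (estimate -0.074). Calls lost in that setting therefore do not measure correlation between genes alone. Fry, which tests a list against no change and not against other genes, placed 5. They were the DAF-16 raised targets (fry adjusted p = 0.0121), neuron markers and thaumatins (0.0302 each), and C-type lectins and glutathione S-transferases (0.0407 each). Thaumatins had not passed camera. Fry did not pass the lysozyme (0.0678), ribosomal (0.0718), oocyte, meiosis, proteasome or vitellogenin lists (0.121 each).

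At the level of single spots, limma called 3711 of 44123, 2364 higher and 1347 lower. Of the 16958 spots with no gene name here, 1318 were called, 710 higher and 608 lower. A term for the dye, separate from that for the bacterium, was past the threshold for 0 genes in limma. At an unadjusted p under 0.05 it held for 2110 of 15042 genes, more than chance alone would pick at that limit. In the simulated data that term found 106 of 200 dye effects of 1.5. The 0 calls therefore do not show that dye effects are absent.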

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

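The tests weighed here were chosen after their results were seen, except the turning of array signs. With 4 arrays, an array was picked out where its gap to the nearest other exceeded Dixon's critical share of the range. Of 123 sets of 4 values tested this held for 4, and chance picks out about 1 in 20. Replicate 4 stood above the others for cnc-10, at 2.09 against 1.32 to 1.43. Replicate 2 stood below the others for F53A9.8, at 3.05 against 5.39 to 5.73. Replicate 2 also stood below the others in the mean of the methionine cycle list, at -0.87 against -0.02 to 0.06, and of the histone list, at -0.89 against -0.29 to -0.19.

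Replicate 2 lay far below the other arrays in many lists of expressed genes. Dye orientation alone argues poorly for the gap between replicates 1 and 2, which share it. They differed by a median of 1.63 over the oocyte and eggshell genes, against 0.37 between replicates 3 and 4. A part that goes with orientation stays open. Spots lower by more than 2-fold made up 15.7% and 21.9% in replicates 1 and 2, against 3.2% and 3.6% in replicates 3 and 4. The median gap of replicate 1 to the dye-swapped arrays was -0.66 in the oocyte list and -0.46 in the vacuolar ATPase list. It was 0.35 in the ribosomal list, the other way. A wider scale of ratios would keep the sign, yet the upper quartile of the vacuolar ATPase genes, a list picked after its values were seen, was -1.04 in replicate 2 while the lower quartile of the mean of replicates 3 and 4 was 0.20. An offset that depends on brightness stays open: replicate 2 lay -0.76 from the dye-swapped arrays in the ribosomal list and -2.30 in the oocyte list, but no intensities were used here to order these by. A biological difference of that pair of cultures was not tested.

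The oocyte, meiosis and ribosomal lists had lower means and the neuron marker list a higher one. The centring of the ratios moves all genes of an array alike, but the oocyte and eggshell median lay below the muscle marker median on all 4 arrays (mean difference -1.23, SD 0.80), as did the ribosomal median (-1.01, SD 0.34). That holds against muscle and not every list: the oocyte means (-1.28, -2.86, -0.84 and -0.64) were not below the proteasome means (-1.39, -2.89, -0.90 and -0.70). A lower share of germline RNA as the only difference would raise muscle and neuron markers alike. These moved apart on all 4 arrays (neuron minus muscle 0.81, SD 0.53), by 1.56 in replicate 2 and 0.33 to 0.73 on the others. An offset that depends on brightness could also part them, and no intensities were used here to weigh it. A smaller germline beside a change in neurons stays open. Younger animals on Bacillus may account for part of it. No growth rate was available here, and any difference in growth would go with the bacterium in this design. Youth therefore cannot be told apart from an effect of the food. It needs the sperm median at or above 0 with the vitellogenin median below 0 on all 4 arrays, and this held on 3.

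The gene calls were set against the 8 ways of turning the signs of the 4 arrays. The real orientation gave 1306 genes and was the 1 turning with that many, the highest of the others giving 0 in limma (397 at an unadjusted p under 0.05). With 8 turnings a share under 0.05 cannot be reached. All array pairs correlated positively before any turning, so turning an array sets it against the others. Fewer calls in the other turnings were thus bound to result, and the comparison does not weigh chance.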

How the results depend on the processing

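The 2 centrings on gene lists were chosen after seeing the data; the other settings were planned. Against 1306 called genes (967 higher, 339 lower; 74.0% higher) and 3711 spots, a dye term gave 3938 genes (1415 and 2523; 35.9% higher) and 11300 spots, and equal scale 4425 (1518 and 2907; 34.3%) and 12045. Array weights gave 2518 (1583 and 935; 62.9%) and 6792 spots, and the dye-swapped arrays alone 2889 (1334 and 1555; 46.2%) and 8286. The forward arrays alone gave 0 genes (0 higher, 0 lower) and 0 spots in limma, with 4204 genes and 12117 spots at an unadjusted p under 0.05. Leaving out 1 replicate gave 0 to 1733 genes, 0 to 1079 higher and 0 to 654 lower, and 56 to 5548 spots. The 0 came without replicate 1, 3 or 4, with 3 arrays in the fit (2695, 4269 and 4090 genes at an unadjusted p under 0.05), and the highest without replicate 2. Housekeeping centring raised the median of all genes by 1.15 and gave 11237 genes (11167 and 70; 99.4%) and 33022 spots. Muscle centring raised it by 0.33 and gave 4043 (2250 and 1793; 55.7%) and 6148. Genes with at least 2 spots of one sign gave 474 of 3200 (305 and 169), and a 2-fold limit 607 (465 and 142). The filter on sign uses the tested ratios themselves, which favours changed genes. An adjusted p under 0.01 gave 4, all 4 higher and 0 lower: lys-10 and, named after their values were seen, R10E8.6, T26H5.9 and T27E4.7. The 1306 calls were all shared with the dye term and the array weights, and 1298 with equal scale. Median centring, the robust prior and the median over spots stayed within 1.5 times (1364, 1110 and 1283 genes). Of 40 lists 19 passed in the main setting, 0 with an estimated correlation (1 at an unadjusted p under 0.05; 5 by fry). Of the 70 called genes named here, 70 kept their direction and lost the call without replicate 1, 3 or 4 and on the forward arrays alone, and 62 kept it without replicate 2. Housekeeping centring reversed end-3 (0.51), grd-4 (0.75), his-69 (0.71), hsp-6 (0.15), hsp-60 (0.021), K08D8.5 (0.21), kat-1 (0.14), mce-1 (0.70), sdz-37 (0.79) and the reticulum chaperone (0.22) and respiratory chain lists (0.40), as it raises all genes. The vacuolar ATPase list ranged from -0.36 without replicate 4 to 0.30 without replicate 2 and was -0.72 on the forward and 0.44 on the dye-swapped arrays alone. The P450 list ranged from -0.011 without replicate 3 to 0.11 without replicate 2 and was -0.028 on the forward arrays alone. The peroxisome and acyl-CoA synthetase list turned to -0.054 on the forward arrays alone. The cause was not tested for the dye term, scale, weights, orientation or these lists. The dye effect stayed at 0 genes in limma after median centring and equal scale (2110 at an unadjusted p under 0.05 in the main setting). That does not exclude dye effects. Requiring values on 3 of 4 arrays was not run, because 0 spots had values on some arrays only. No paired analysis was possible because each array is already 1 pair of RNAs and no groups share replicate numbers. Signal over background was not used here, so its limit on dim genes is unknown.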

Other observations

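Gene families not used to define the fixed lists were grouped by name and tested, a step chosen after seeing the data. Of 267 nuclear hormone receptor genes (nhr), 3 of them on fixed lists and not called, 70 rose and 2 fell, or 26.2% higher against 6.43% of all genes (one-sided Fisher's exact test, adjusted p = 4.85e-23 over 87 families of at least 10 genes). The highest were nhr-168 (3.15 ± 0.64, SD, n = 4), nhr-99 (2.56 ± 0.61) and nhr-179 (2.45 ± 0.42), while the family's median was 0.09. Of 189 F-box genes of the fbxa family, whose products recruit proteins for ubiquitination, 28 rose and 2 fell (14.8% higher, adjusted p = 0.00128), with fbxa-24 at 2.84 ± 0.32. Of 46 math genes, named for the MATH protein domain, 10 rose and 0 fell (21.7% higher, adjusted p = 0.0163), with math-38 at 3.73 ± 0.49 and math-34 at 2.76 ± 0.53. Of 41 neuropeptide-like protein genes (nlp), 9 rose and 0 fell (adjusted p = 0.0212), with nlp-20 at 2.91 ± 0.97 and nlp-10 at 2.59 ± 0.37. Of the 41, 11 are on the fixed list of antimicrobial peptides and 0 of these 11 were called by limma. The fixed list of neuron markers, which holds other neuropeptide genes, had 16 of 46 higher. The oocyte and meiosis lists had lower means (-1.41 and -1.52), and whether a lower share of germline RNA accounts for these families was not tested. The family tests count genes as independent, which members of a family with similar sequence are not. They also rest on calls that limma did not make without replicate 1, 3 or 4 (0 genes each).

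Among genes called lower, 0 of the 87 families passed (one-sided Fisher's exact test with Benjamini-Hochberg adjustment). The nearest was the set family, named for the SET domain of histone methyltransferases, with 5 of 32 genes lower and 0 higher (15.6% against 2.25% of all genes, Fisher's exact p = 0.000689, adjusted p = 0.0599). One member of the oocyte and eggshell list went against the rest: cpg-7, picked after its value was seen, measured 2.90, 2.14, 3.02 and 0.93 in replicates 1 to 4, a mean of 2.25 that did not pass (adjusted p = 0.0506), whereas the mean of the list was -1.41.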
